A study of Oryza sativa with 2 samples.

How the data were processed

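Leaf RNA of 2 groups of rice seedlings, cultivar indica 9311, was measured on 1-colour oligonucleotide arrays, 1 array for nontransgenic and 1 for OsEATB transgenic plants. Per the labels, 10 seedlings at the 4-leaf stage were taken for each group after growth at 28 °C in diluted Murashige and Skoog medium under 14 h of light and 10 h of darkness. Total RNA was column-purified and biotin-labelled cRNA was made with a 3′ in vitro transcription kit, per the labels' protocols. The signals were made with MAS5, per the submitters' processing notes. Its version, the scaling target and detection calls are not given in the sources used here. The deposited values are on a log2 scale, as their range and their linear means show: unlogged, both arrays had the same mean of 499.9 after 2% of the values were trimmed at each end. The authors' scaling therefore removes any overall difference in brightness between the arrays. The per-sample columns not mapped to a group numbered 0.

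Control probe sets of the array maker (187) were set apart. Each remaining log2 signal below the 40th percentile of its array was raised to that percentile (4.41 on the nontransgenic and 4.61 on the transgenic array), and a ratio with 1 side at this floor is given as a lower bound. A probe set passed the level filter if it reached the median of its array on at least 1 array. The log2 ratio was the transgenic minus the nontransgenic value. A threshold of 2-fold was used throughout. A gene was represented by its probe set with the highest mean signal.

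Probe sets were named through the platform's gene table, updated by gene number through a reference of rice genes (assembly ASM3414082v1), which served for names and for which genes neighbour each other. Of the probe sets, 22436 had 1 gene, 95 had several and 34663 had none in that table. They stood for 17905 genes, all found in the reference, of which 2457 had a descriptive name. A total of 15192 genes passed the filter, 2147 of them named. OsEATB was matched by neither name nor locus and is not analysed here.

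With 1 array per group no test between groups exists, and none was run. For each gene list, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from genes matched on brightness in 20 bins. A percentile under 1 or over 99 was called an edge. Such percentiles describe these arrays only, and with 41 lists some edges arise by chance. In simulations on the same genes, 5 of 200 unchanged lists of 20 genes passed an edge, and 50 of 50 lists shifted by 0.5 did so. Those ratios were drawn independently for each gene, so the simulations do not cover lists of genes regulated together. The shift of 0.5 is also larger than the median of every edge list found here except diterpenoid phytoalexin synthesis. In simulated arrays all 200 bright probe sets changed by 1.5 on the log2 scale were recovered, with 0 others called. There every log2 ratio had an SD of only 0.2, against a scatter of 0.76 between dim probe sets of 1 gene here. This checks the counting and says nothing on how many 2-fold ratios arise from scatter. The central 95% of random medians was taken as the spread of a list. For genes near one another, ratios were shuffled 10000 times within the brightness bins. In simulations with 130 marked genes, 1 of 40 random placements and 40 of 40 with planted neighbours exceeded the range of the shuffles. Brightness bins were assigned at random there and planted neighbours lay side by side. The simulations therefore check the counting and not the matching on brightness or weaker grouping.

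The lists were fixed before the data were examined by gene function, tissue and literature. The reference gives symbols without descriptions, so that members were matched by symbol, after the value table had been opened but before any gene ratio was seen. Lists of plastid ribosomal proteins and transposable elements could not be filled in this way and are not used here. Of the 41 lists, 30 were fixed in advance and 11 families were added from the symbols at that point: cell wall synthesis, senescence, brassinosteroid, endoplasmic reticulum folding, tubulin and actin, potassium transporters, aquaporins, calcium signalling, protein phosphatases, zinc finger proteins, and metallothioneins with thioredoxins.

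Genes were named by a rule fixed in advance. It took OsEATB, the gibberellin biosynthesis genes, members of the gibberellin, ethylene and tillering lists with a 2-fold ratio, the 10 largest rises and 10 largest falls among genes with a descriptive name, and up to 4 genes of each other list with at least 3 members at 2-fold. For the largest rises and falls, the brighter array had to reach its 75th percentile and all passing probe sets of the gene had to go the same way. The rule took 95 genes. Further list members, among them Hd3a, are given with their signals or log2 ratios, as examples chosen after their values were seen.

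Alternatives covered the floor (none, at the median, or a pseudocount of 16), normalization (median centring, quantile, lowess), the level filter (none, or the 75th percentile), thresholds of 3-fold and 1.5-fold, averaging of probe sets, and omission of probe sets with suffixes for several transcripts. Centring on the hybridisation controls and random lists drawn from named genes were added after seeing the data. Median centring and hybridisation-control centring subtract the same value from every gene, so neither can move the percentile of a list. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.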

Results

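Leaf RNA was profiled from rice seedlings of the indica cultivar 9311 that carried an OsEATB transgene and from nontransgenic 9311 seedlings. OsEATB is an ERF-family transcription factor that the rice literature ties to ethylene, gibberellin synthesis, internode length and tillering. Each group was represented by 1 array, hybridised with RNA from the leaves of 10 seedlings at the 4-leaf stage, so that a ratio has no replicate behind it and no p-value or standard error was computed. The number of arrays limits the precision of every value given here. Each array held 57381 probe sets, of which 187 were controls of the array maker. The linear signals had a trimmed mean of 499.9 on both arrays, and the median log2 signal was 5.16 on the nontransgenic and 5.32 on the transgenic array. Across the 32299 probe sets that passed the level filter, the log2 signals of the arrays correlated with a Pearson r of 0.891, a value across probe sets, which are not independent replicates.

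The transgene itself was not analysed here, because no probe set was tied to OsEATB by the names used. The group labels therefore stand without a check from the targeted gene.

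The comparison of the transgenic with the nontransgenic array asked which leaf transcripts differ when OsEATB is introduced. Among named genes, LEA19, PIN4, EIL1 (LOC4332697) and RAB21 had the largest ratios, with lower bounds taken as they stand. LEA19, a late embryogenesis abundant protein, had a signal of 4.49 on the nontransgenic array and 6444 on the transgenic array, at least 302-fold higher. The dehydrin gene RAB21 was 33.6-fold higher in the transgenic leaves, with log2 signals of 5.75 and 10.82. Isocitrate lyase (ICL) and malate synthase (MS), enzymes of the glyoxylate cycle, for which no list was fixed, had log2 ratios of 4.17 and 3.02, the latter 8.11-fold higher. EIL1 (LOC4332697), which encodes an EIN3-like factor of the ethylene pathway, was 48.1-fold lower, at log2 signals of 11.50 and 5.91.

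In total, 922 of 15192 genes were at least 2-fold higher and 674 were at least 2-fold lower in the transgenic leaves. The value on the other array lay at the background floor for 346 of the higher and 183 of the lower genes, and those ratios are lower bounds. At the level of probe sets, 3555 were higher and 2301 lower. The median log2 ratio over passing probe sets was -0.02. The split between higher and lower depended on scaling and on the floor. Higher probe sets were 60.7% of those that differed by 2-fold, and 45.8% after lowess centring on brightness, while higher genes went from 57.8% to 50.8%. Without a floor higher probe sets were 53.4%, and with the pseudocount they were 53.9%.

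**Figure D1:**
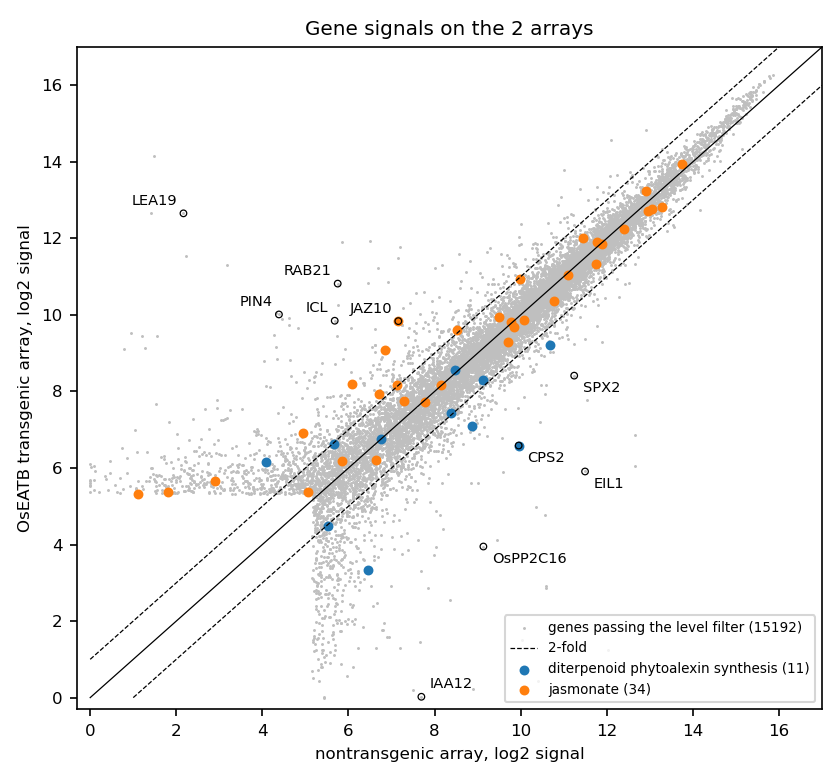
Log2 signal of 15192 genes on the nontransgenic array (x axis) and on the OsEATB transgenic array (y axis), 1 point per gene and 1 array per group. Dashed lines mark 2-fold differences, filled coloured points are the 11 diterpenoid phytoalexin and 34 jasmonate genes, and ringed genes include LEA19, at least 302-fold higher, and CPS2, 10.3-fold lower, in the transgenic leaves.

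Ratios of 2-fold or more were far more frequent among dim genes. With the genes ranked by mean signal and divided into 4 equal groups, 28.8% of the dimmest 3798 genes differed by 2-fold or more, against 8.40% and 3.29% in the following groups, and 39 genes were higher and 18 lower among the brightest 3798. Probe sets of 1 gene gave a measure of scatter within the arrays. They read the same RNA on the same arrays and are not replicates of the plants. The spread between plants or between hybridisations therefore does not enter it. Among 2414 genes with several passing probe sets, the brightest and the next had the same sign of ratio in 60.2%, and in 65.7% of the brightest of 3 equal groups. Of 186 such genes with a 2-fold ratio on the brightest probe set, the next had the same sign in 138 and was itself 2-fold different in 85. The scatter of a log2 ratio between such probe sets was 0.76 in the dim, 0.36 in the middle and 0.22 in the bright group.

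Other named genes with large ratios and bright signals belonged to varied processes. Higher in the transgenic leaves were the auxin efflux gene PIN4, at least 48.4-fold, the peroxygenase gene PXG, 22.9-fold, and the early nodulin-like gene ELA3, 7.43-fold. The metallothionein gene MT1B was 6.84-fold higher and reached a log2 signal of 13.78. JAZ10, a repressor of jasmonate responses, was 6.41-fold higher, and the beta-glucosidase gene BGLU26 was 5.63-fold higher. Lower were the protein phosphatase gene OsPP2C16, with a log2 ratio of -4.52 or lower, the Aux/IAA gene IAA20 (LOC4327919), 9.40-fold, and SPX2, a regulator of phosphate responses, 7.11-fold. The chitinase gene Cht11 was 4.67-fold lower, the pathogenesis-related gene PBZ1 was 3.54-fold lower, the glutaredoxin gene GRXS2 was 3.38-fold lower and the potassium transporter gene HAK10 was 3.28-fold lower. PBZ1 kept a log2 signal of 10.46 in the transgenic leaves. LEA19, RAB21, JAZ10 and GRXS2 were read by probe sets that may hybridise to several transcripts, and LEA19 and GRXS2 had no other passing probe set. The same holds for OPR1, RR4, HSP18.1 and HXK4 (LOC4326776), given below. With such probe sets left out, JAZ10 had a log2 ratio of 1.79 in place of 2.68, and RAB21 had 7.34 in place of 5.07. With the floor raised to the median, which makes lower bounds smaller, LEA19, PIN4 and OsPP2C16 had log2 ratios of 7.49, 4.85 and -3.82, and PIN4 had 4.83 with the pseudocount.

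Genes that reached the 75th percentile of an array, with all passing probe sets going the same way, were also ranked regardless of name. The largest ratio in each direction belonged to a gene without a descriptive name. LOC4329983 had a log2 signal of 1.49, below the floor, on the nontransgenic array and 14.15 on the transgenic array, at least 850.1-fold higher, and LOC4346183 was at least 302-fold higher. LOC4330063 was at least 171-fold lower and LOC4325244 was 97.0-fold lower. These 4 genes lie outside the rule for named genes and were chosen after their values were seen.

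Gibberellin biosynthesis was examined because OsEATB has been tied to it. Of 8 measured genes, 1 was at least 2-fold higher and 1 at least 2-fold lower. GA20OX2, the gibberellin 20-oxidase of the semi-dwarf locus, was 2.77-fold higher, at log2 signals of 6.12 and 7.59. CPS2, an ent-copalyl diphosphate synthase that stands in the phytoalexin list as well, was 10.3-fold lower, at 9.95 and 6.59. Its lower signal therefore cannot be read as a change in gibberellin synthesis. A ratio as large as that of CPS2 was found in 0.658% of genes of like brightness, and one as large as that of GA20OX2 in 10.1%. The other members had smaller ratios. CPS1, which supplies the gibberellin pathway, was dim on both arrays, at 4.43 and 5.38. The kaurene synthase gene KS1A had a log2 ratio of -0.40. The cytochrome P450 genes CYP701A8, CYP701A19 and CYP88A5 had -0.82, -0.38 and 0.23, and GA20OX3 had 0.43. CYP701A8 stands in the phytoalexin list as well, so its ratio cannot be read as a change in gibberellin synthesis either. The median log2 ratio of the 8 genes was -0.08, at percentile 45.2 of 10000 random gene lists matched on brightness. Across the alternatives fixed before the data were examined and with random lists of named genes, that percentile ranged from 7.85 to 88.8.

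Of 12 gibberellin inactivation and signalling genes, 0 were 2-fold higher and 1 was 2-fold lower, with a list median of 0.08 at percentile 81.3. The lower gene was SLRL1, a DELLA-like repressor, with a ratio of at least 2.92-fold that rests on a dim signal of 6.16 and is below 2-fold with the floor at the median. The DELLA gene SLR1 stood at 10.12 and 10.26, the receptor gene gid1 at 10.77 and 11.23, and the inactivating enzyme gene CYP714D1 at 7.28 and 6.43.

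Among 9 ethylene genes, EIL1 (LOC4332697) was the 1 with a 2-fold ratio. A further gene with the name EIL1, LOC107276358, stood at 14.78 and 15.02. The receptor genes ETR2, ERS1 and ERS2 had log2 ratios of -0.04, -0.24 and -0.13, and EIN2 had -0.13. The list median was -0.04, at percentile 39.9. Of 10 AP2/ERF genes in the list, 0 had a 2-fold ratio, and their median was 0.03, at percentile 59.2. Without probe sets that may hybridise to several transcripts it was 0.55, at percentile 97.7.

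Among 10 tillering and strigolactone genes, MADS57, a MADS-box factor that acts on tillering, was 2.74-fold higher, and TAC1, which sets tiller angle, was 3.83-fold lower. The strigolactone receptor gene D14 stood at 14.44 and 14.74, the F-box gene D3 at 8.88 and 9.35, and CCD7, which acts in strigolactone synthesis, at 7.95 and 7.84. The list median was 0.05, at percentile 53.8.

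**Figure D2:**
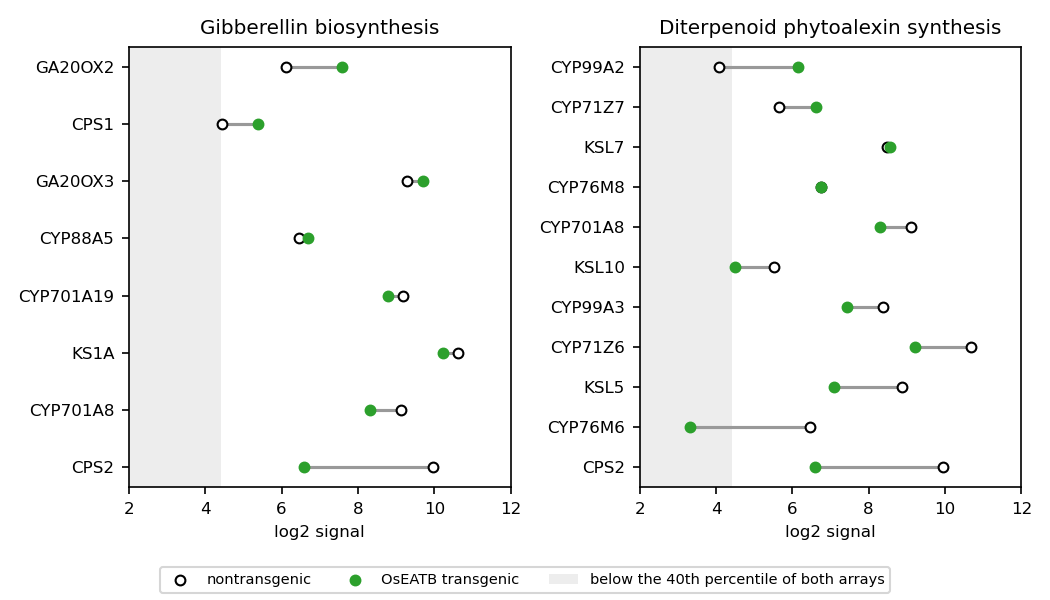
Log2 signals (x axis) of the gibberellin biosynthesis genes and of the diterpenoid phytoalexin genes (y axis) on the nontransgenic array (open points) and on the OsEATB transgenic array (green points), 1 array per group. The grey band lies below the 40th percentile of both arrays. CPS2, which stands in both lists as CYP701A8 does, is at 9.95 on the nontransgenic and at 6.59 on the transgenic array.

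Diterpenoid phytoalexin synthesis stood lowest of the 41 gene lists. Of 11 measured genes, 4 were at least 2-fold lower and 1 was at least 2-fold higher in the transgenic leaves. After CPS2, the kaurene synthase-like gene KSL5 was 3.42-fold lower, at 8.87 and 7.10, and the cytochrome P450 gene CYP71Z6 had a log2 ratio of -1.45, at 10.67 and 9.22. CYP76M6 was at least 3.58-fold lower, with a log2 ratio of -1.14 with the floor at the median. CYP99A2 was at least 3.34-fold higher from a dim signal, and below 2-fold with the floor at the median. KSL7, at 8.47 and 8.55, and CYP76M8, at 6.76 on both arrays, differed little. The list median was -0.92, and 0 of the 10000 random lists had a lower one. Of the 11 genes, 7, with all 4 lower ones among them, lie in 1 cluster around CPS2. Random lists were drawn without regard to position, so the percentile may overstate how unusual this list is. In 10 of 11 alternatives the percentile stayed below 1, and it was 6.64 without the level filter. Median centring, 1 of the 10, could not have moved it.

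Jasmonate genes had the highest percentile of the 41 lists, though not the highest median. Of 34 genes, 8 were at least 2-fold higher and 0 at least 2-fold lower, with a list median of 0.25 at percentile 99.9. Besides JAZ10, the lipoxygenase genes CM-LOX1 and CM-LOX2 were 4.72-fold and 3.91-fold higher and the oxophytodienoate reductase gene OPR1 was 4.33-fold higher. Other members had smaller ratios, among them JAZ1 at 13.74 and 13.95 and the allene oxide cyclase gene aoc at 13.05 and 12.78. Restricted to genes at or above the 75th percentile of an array, the list median was -0.03, at percentile 37.5, and after lowess centring it was 0.11, at percentile 91.0. The percentile was 98.3 without probe sets that may hybridise to several transcripts, 96.1 with quantile normalization and 87.5 without the level filter. In 6 of 11 alternatives it stayed above 99.

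Pathogenesis and defence genes had a list median of 0.27 at percentile 99.8, with 5 of 25 at least 2-fold higher and 2 lower. CEBIP, the receptor for chitin fragments, was 3.42-fold higher, at 10.63 and 12.40, and the chitinase gene LOC4342115 was 4.27-fold higher. Cht11 and PBZ1 were the 2 lower members. The percentile was 89.5 without probe sets that may hybridise to several transcripts, and 6 of 11 alternatives kept it above 99. Median centring, 1 of these 6, could not have moved it. Of 6 WRKY genes, WRKY62 and WRKY76 had log2 ratios of 1.76 and 1.52, and the list median of 0.35 lay at percentile 95.01. Phenylpropanoid and lignin genes had a list median of -0.18 at percentile 3.55, with 1 of 20 higher and 1 lower.

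Auxin genes were lower as a list in every alternative tried. Of 50 genes, 3 were at least 2-fold higher and 7 at least 2-fold lower, 13 had a ratio above 0, and the list median was -0.25 at percentile 0.04. IAA20 (LOC4327919) and IAA12, which was at least 8.46-fold lower, were among the lower Aux/IAA genes. With the floor at the median, IAA12 had a log2 ratio of -2.38. GH3.2, which conjugates auxin to amino acids, was 4.34-fold higher, against the direction of its list, as was PIN4. Other Aux/IAA genes had smaller ratios, among them IAA17 at 14.56 and 14.15 and IAA3 at 14.12 and 13.74. Centred on the hybridisation controls, the list median was -1.16 beside a shift of all genes to -0.92, with the percentile as before.

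Cytokinin genes had a list median of 0.13 at percentile 96.6, with 2 of 26 higher and 2 lower. The response regulator genes RR4 and RR2 were 3.36-fold and 2.71-fold higher, and LOGL9 and LOGL10, which activate cytokinin, were 3.34-fold and 2.32-fold lower. Brassinosteroid genes, 17 in number, had 0 members with a 2-fold ratio and a median of -0.04 at percentile 49.7.

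Of 25 abscisic acid and dehydration genes, 3 were at least 2-fold higher and 0 lower. They were LEA19, RAB21 and its relative RAB16B, which was 8.26-fold higher. The remaining members had ratios under 2-fold, including Dhn1 at 10.96 and 11.80 and P5CS1 at 12.28 and 12.25, and the list median of 0.13 lay at percentile 96.7, in a range of 46.3 to 97.2 over the alternatives. Of 42 heat shock genes, 4 were higher and 0 lower. HSP23.2 was at least 3.22-fold and HSP18.1 at least 2.94-fold higher, both from dim signals and both below 2-fold with the floor at the median, and the list median of 0.13 lay at percentile 94.98, in a range of 50.9 to 95.5.

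Genes of photosynthesis and ribosomes differed by less than 2-fold. The 12 light-reaction genes had a median log2 ratio of 0.37 at percentile 99.7. The plastocyanin gene PETE stood at 15.34 and 15.82 and the chlorophyll-binding protein gene LHCP at 15.40 and 15.83. Quantile normalization brought the list median to 0.01, at percentile 51.0, and lowess centring to 0.11, at percentile 89.0. The 25 cytosolic ribosomal protein genes had a median of -0.16 at percentile 0.05, and 0 of them had a 2-fold ratio. RPL30 stood at 12.72 and 11.96 and RPS7 at 13.06 and 12.73. The 7 carbon fixation genes had a median of 0.25 at percentile 81.5 and the 16 chlorophyll synthesis genes one of -0.06 at percentile 8.77. Of 58 cell cycle and histone genes, 4 were higher and 3 lower, with a median of -0.10 at percentile 13.2.

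**Figure D3:**
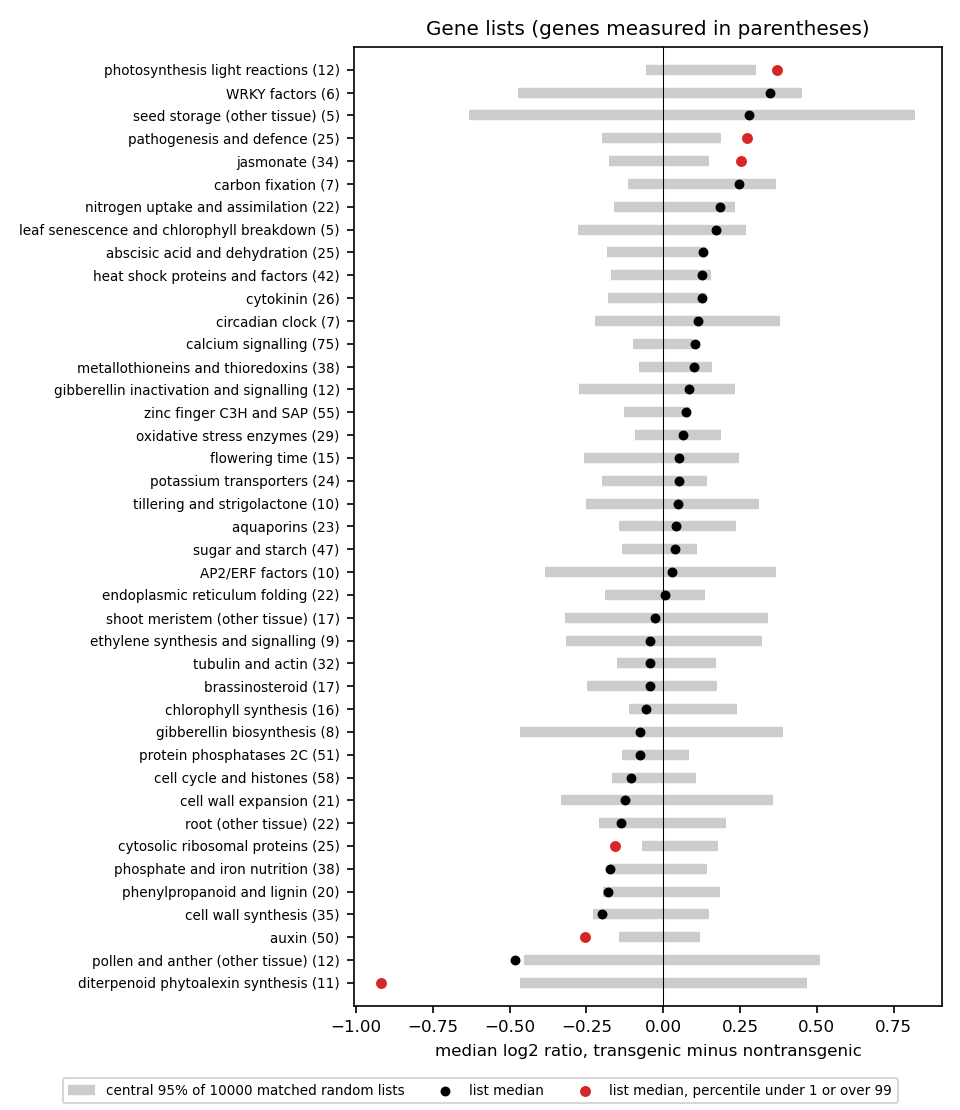
Median log2 ratio, transgenic minus nontransgenic (x axis), of 41 gene lists (y axis, genes measured in parentheses), 1 array per group. Grey bars span the central 95% of 10000 random lists matched on brightness, and red points mark the 6 lists with a percentile under 1 or over 99, from diterpenoid phytoalexin synthesis at -0.92 to photosynthesis light reactions at 0.37.

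Among cell wall expansion genes, 3 of 21 were higher and 4 lower. EXPB2 was at least 6.06-fold and EXPB7 3.81-fold lower, while EXPB6 was 3.21-fold and EXPA3 at least 2.48-fold higher, the last below 2-fold with the floor at the median. The list median was -0.12 at percentile 22.2, and 0.29 at percentile 88.8 without probe sets that may hybridise to several transcripts. Among 38 phosphate and iron genes, 3 were higher and 5 lower, with a median of -0.17 at percentile 2.65. Over the alternatives that percentile ranged from 0.01 with the 75th-percentile level filter to 61.2 without probe sets that may hybridise to several transcripts. After SPX2, the phosphate exporter gene PHO1-2 was 2.41-fold lower, with a log2 ratio of -0.80 as the mean over its probe sets, SPX3 had a log2 ratio of at least 1.85 and the vacuolar iron transporter gene VIT1.2 was 3.19-fold higher. Nitrogen genes, 22 in number, had 1 higher member and a median of 0.19 at percentile 92.6, and at 99.87 without probe sets that may hybridise to several transcripts. Of 47 sugar and starch genes, the sugar transporter gene SWEET14 was 2.54-fold lower, the granule-bound starch synthase gene GBSS1 was 2.05-fold lower, but less than 2-fold with lowess, quantile normalization or the pseudocount, and the hexokinase gene HXK4 (LOC4326776) was 2.38-fold higher. Their median was 0.04 at percentile 77.95. Of 29 oxidative stress genes 1 was higher, with a median of 0.06 at percentile 61.8.

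Of 7 clock genes, whose transcripts follow the time of day, PCL1 stood at 4.94 and 6.94, both dim, while CCA1 stood at 15.32 and 15.44, PRR73 at 13.69 and 13.49 and GI at 12.74 and 12.45. The list median was 0.11 at percentile 57.9, and it turned to -0.23 with quantile normalization, while the lowest percentile over the alternatives was 2.72. Of 15 flowering genes 2 were higher, among them Hd3a, dim on both arrays at 3.43 and 5.89, and the median was 0.05 at percentile 69.3.

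Markers of other tissues did not stand at an edge. Shoot meristem genes had a median of -0.03 at percentile 42.8, with 3 of 17 higher and 2 lower. WOX11 was 2.53-fold lower and OSH6 was 2.47-fold higher, but less than 2-fold with the floor at the median or the pseudocount. Root genes, with 0 of 22 higher and 2 lower, had a median of -0.14 at percentile 9.55. The 5 measured seed storage genes had a median of 0.28 at percentile 81.6. Pollen and anther genes, with 2 of 12 higher and 4 lower, had a median of -0.48 at percentile 1.90. MADS58 was 3.49-fold higher, MADS16 was 2.49-fold lower and MADS4 was 2.32-fold lower, but less than 2-fold with the pseudocount. Of these lists, pollen and anther alone lay below percentile 5 or above percentile 95.

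The control probe sets measured differences between the arrays themselves. All 27 hybridisation controls, bacterial and phage transcripts added in fixed amounts, were brighter on the transgenic array, by a median of 0.90 on the log2 scale (SD 0.14 across probe sets). The poly-A controls, added to the RNA before labelling, were higher by a median of 0.49 and the ribosomal RNA probe sets by 0.09. If the arrays were centred on the hybridisation controls, 199 genes would be at least 2-fold higher and 6263 lower. The difference between 3′ and 5′ probe sets is used as a sign of RNA integrity. It was larger on the transgenic array by 0.80 for actin and smaller for gapdh, at -0.64. On the nontransgenic and transgenic arrays this log2 difference was 3.56 and 4.36 for actin and 4.85 and 5.51 for another actin set. It was 3.26 and 2.61 for gapdh, but 0.94 and 0.84 for cyclophilin and -0.19 and -0.05 for ubiquitin. For the poly-A controls it was 4.29 and 4.47 for dap and 0.45 and 0.11 for lys. Since dap was added and not part of the leaf RNA, a large difference here cannot be read as leaf RNA integrity alone.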

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

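All tests in this part were chosen after the results were seen. Of the reporter probe sets of the array maker, which match foreign sequences and lie outside the main measurement, 2 reached the median of the transgenic array and were at least 2-fold higher there. Their log2 ratios, taken without the floor, were 1.21, from 5.33 to 6.54, and 1.57, from 3.85 to 5.42. The signal of 3.85 lies below the nontransgenic floor of 4.41, so the second ratio would be smaller with the floor. Of 64 reporter probe sets, 7 reached the median of an array, and of these 2 were at least 2-fold higher and 2 at least 2-fold lower, again without the floor. The 2 lower ones had transgenic signals of 4.14 and 1.82, below the floor of 4.61, and would be less than 2-fold lower with it. Scatter of dim probe sets is a candidate explanation. With no floor on either side, 17.6% of rice probe sets of like brightness had a ratio of 1.57 or more, and 8.68% of those like the brighter reporter had one of 1.21 or more. A reporter sequence carried by the construct stays open. The brighter reporter shares its source with 2 other probe sets, which had a median log2 ratio of -0.88 and were too dim to decide. The reporter with the ratio of 1.57 has no other probe set of its source, so nothing could be checked for it.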

How the results depend on the processing

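Centring on the hybridisation controls and random lists of named genes were chosen after seeing the data. Under hybridisation-control centring, 575 probe sets and 199 genes were higher and 14074 and 6263 lower, and the median log2 ratio of genes was -0.92. The medians of the gibberellin biosynthesis and the gibberellin inactivation and signalling lists became -0.98 and -0.82, and the jasmonate, defence and light-reaction medians turned to -0.65, -0.63 and -0.53. The same subtraction for every gene is the cause there, and no percentile moved. With the 75th-percentile level filter, which tests fewer genes, 526 probe sets and 297 genes were higher and 403 and 218 lower, 5 lists passed the low edge, among them tubulin and actin and phosphate and iron nutrition, and the jasmonate median turned to -0.029. A floor at the median gave 1695 and 1305 probe sets, a 3-fold threshold 1061 and 599, and a 1.5-fold threshold 6130 and 5669, by construction. In place of 3 lists, 0 passed the high edge after lowess or quantile normalization, 1 without a level filter and 1, nitrogen genes in place of those 3, without probe sets read by several transcripts. HAK22, 4.19-fold lower on its brightest probe set, had a log2 ratio of 1.82 without such probe sets. The cause was not tested for these edges and for HAK22. Without the level filter, 921 of the 922 higher and all 674 lower genes were kept. Of 89 named genes with a 2-fold ratio, 65 kept it the same way under each alternative fixed in advance that gave a value, and 24 were below 2-fold in 1 or more, 14 of them with 1 side at the floor. Counted once per list and alternative, 389 medians moved by less than the spread of random lists and 51 by more, most of the latter under hybridisation-control centring. The 4 given above, which belong to the 3 lists past the high edge, turned sign. Other medians turned sign too, among them those of the clock and cell wall expansion lists. Of the 922 higher and 674 lower genes, 810 and 648 were kept with quantile normalization, 755 and 627 with lowess, 922 and 660 with median centring and 199 and 674 with hybridisation-control centring. No paired analysis was possible because each group had 1 array, and leaving out an array would leave no comparison. Signals close to background limit what can be said of dim genes, in which most 2-fold ratios arose.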

Other observations

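The tests of explanations and the neighbour counts in this part were chosen after the results were seen. Several gene families that were added to the lists from their symbols contained genes with large ratios. Of 75 calcium signalling genes, 11 were at least 2-fold higher and 2 lower, with a median of 0.10 at percentile 98.5. The calmodulin-like genes CML31, CML24 and CML15 were 4.04-fold, 3.74-fold and 3.70-fold higher, and CML11 was 2.88-fold lower. Among 51 protein phosphatase 2C genes, 0 were higher and 4 lower. After OsPP2C16, OsPP2C36 was 2.79-fold, OsPP2C08 2.35-fold and OsPP2C69 2.23-fold lower, and the list median was -0.08 at percentile 17.95. Of 38 metallothionein and thioredoxin genes, 4 were higher and 1 lower, among them GRXC10 at 3.15-fold and GRXS9 at 2.16-fold higher, with a median of 0.10 at percentile 84.1. Of 55 zinc finger genes, OsC3H10 was at least 6.03-fold and OsC3H40 3.16-fold higher, both by over 1.5 times less with the floor at the median, and OsC3H39 was 3.07-fold lower, with a median of 0.07 at percentile 95.8.

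Of 24 potassium transporter genes, 1 was higher and 4 lower, among the latter HAK22, which had a log2 ratio of 1.82 without probe sets read by several transcripts. HAK18 was 2.28-fold higher, HAK10 was 3.28-fold lower and the sodium transporter gene HKT1.5 was 2.29-fold lower, with a median of 0.05 at percentile 82.8. Of 23 aquaporin genes, 2 were higher and 3 lower. TIP2-1 was 4.77-fold lower, with a log2 ratio of -1.40 in place of -2.25 without probe sets read by several transcripts, TIP3-2 was 3.01-fold lower and DTE1 was at least 2.25-fold lower (below 2-fold with the floor at the median), while PIP2-4 was 2.19-fold higher. Their median was 0.04 at percentile 45.6. Of 35 cell wall synthesis genes, BC1L9 was 3.76-fold higher, CSLC3 at least 2.33-fold higher and GT43C 2.60-fold lower, the last 2 below 2-fold with the floor at the median and CSLC3 also with lowess, with a list median of -0.20 at percentile 5.04. Of 32 tubulin and actin genes, ADF-10 was at least 2.83-fold higher and FH8 at least 2.05-fold lower, both below 2-fold with the floor at the median, with a list median of -0.04 at percentile 21.9, and -0.35 at percentile 0 with the 75th-percentile level filter. Endoplasmic reticulum folding genes had a median of 0.01 at percentile 66.3. Senescence genes had a median of 0.17 at percentile 90.4, and SGR, which acts in chlorophyll breakdown, stood at 10.47 and 11.85.

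The lower phytoalexin genes were next to one another in the genome. CYP71Z6, CPS2, KSL5 and CYP76M6 lie within 5 measured genes, with CYP71Z7 among them at a log2 ratio of 0.96. CPS2, KSL5 and CYP76M6 were read by probe sets without suffixes for several transcripts, which argues against shared hybridisation as the source for these genes. Without probe sets that carry such suffixes the list stood at percentile 0.01, but this adds little, since these genes stayed in it. Lowess centring gave 0.03, but the random lists were already matched on brightness, so that an offset depending on brightness was hardly tested. A deletion of the whole cluster in the transgenic line is argued against by 3 of the 7 cluster members near CPS2, which were less than 2-fold lower, KSL7, CYP76M8 and CYP71Z7. The genotype stays an open explanation, as does any other difference between the 2 pools of plants, since each was measured once.

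Genes with 4-fold or larger ratios and a bright signal lay near one another more often than shuffled ratios did, at a threshold and reach taken after 90 combinations of threshold, reach, direction and probe sets had been looked at. Of 127 such genes, 33 had another within 5 measured genes, against a mean of 10.1 and a central 95% range of 2 to 19 in 10000 shuffles within brightness bins, and 0 shuffles gave as many. Of the 90 combinations, 36 lay above their range and 54 inside it, among the latter 388 of 512 genes at 2-fold within 20 genes, in a range of 360 to 399, and 8 of 67 at 8-fold within 5 genes, in a range of 0 to 8. Without probe sets read by several transcripts the number at 4-fold was 31 of 122, above the range of 4 to 20, which argues against shared hybridisation as the sole source. A chromosome segment of other origin in 1 of the lines may place higher and lower genes together, but this is not decided, since 11 of 38 lower genes had a higher one within 20 genes, inside the range of 3 to 13, while 16 did without such probe sets, above the range of 4 to 14, and regulation shared by neighbouring or duplicated genes stays open beside it.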
